A study of Mus musculus with 20 samples.

How the data were processed

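Messenger RNA was sequenced in 20 libraries, 5 for each of 4 groups: liver and epididymal white adipose tissue (eWAT) of WT and IR 4A male mice, 2 months old. Per the labels' protocols, RNA was enriched for poly-A, made into stranded libraries in 1 preparation and read as paired 100-base reads, to a planned depth that the counts below reflect. The labels give a replicate number but no animal, so each library was treated as a separate sample, and no library was a duplicate of another (chi-square per degree of freedom of at least 12.5 between libraries of a group, 20 pairs per tissue).

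The deposited count tables hold estimated counts per gene that the authors rounded to whole numbers, limited to genes with a symbol and a sum of at least 10 over the 10 libraries of a tissue. Per the submitters' processing notes Salmon 1.8.0, DESeq2 1.32.0 and the GRCm39 build were used, without their settings. The deposited normalized tables hold values on a log2 scale whose transform is not stated, and were used only for a check: their lowest rank correlation with log2 CPM over libraries was 0.995 in liver and 0.987 in eWAT. The deposited DESeq2 tables give, per the file headers, a mean signal per gene (counts divided by size factors), a log2 fold change with its standard error on the log2 scale, and the p-value with its adjusted form. All columns of values were matched to a sample by tissue, genotype and number, reading Ctl as WT.

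Entries that repeated an Ensembl identifier were dropped (83 in liver, 208 in eWAT), leaving 15608 and 20738 genes. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 12421 genes in liver, 16476 in eWAT and 14695 of the 15349 in both tables for the comparison of tissues. Libraries were scaled by TMM, and CPM values are TMM-scaled. IR 4A was compared with WT in each tissue by edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 (R 4.3.3). Whether the change differed between tissues was tested as the interaction of tissue and genotype in a fit of all 20 libraries, and is given as eWAT minus liver. The common biological coefficient of variation was 0.187 in liver and 0.512 in eWAT, with 4.08 and 1.76 prior degrees of freedom, which is what sets the precision of single genes. The first principal component took 27.9% of the variance in liver and 68.9% in eWAT.

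Before the data were examined, 55 lists were fixed (29 of genes of a process, 26 of cell or tissue markers), as were the comparisons, thresholds and the rule for named genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over lists: 45 in liver, 52 in eWAT and 49 for the difference between tissues. Beside it stand camera with a correlation estimated per list, fry, the number of members past the threshold over all genes, and the number past it when adjusted over the list alone. The level of a list is the mean log2 CPM of its members (prior count 2). Levels and technical measures were compared by exact permutation tests over all 252 splits of 10 libraries, whose smallest p is 0.00794. Named genes were the 10 higher and 10 lower with the largest change among those past the threshold in each tissue, with a mean of at least 1 CPM, no overlap of the groups and an informative symbol, up to 4 members of each list with the smallest adjusted p, the 5 largest and 5 smallest differences between tissues among genes past the threshold with a mean of at least 1 CPM in each tissue and an informative symbol, and 16 genes of insulin action or the checkpoint given whatever their result. Some genes that this rule selects are not reported here.

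The tests were checked on simulated data with 200 changed genes, picked among those with more counts. Genes were drawn independently, without the correlation between genes of real libraries, so the recovery need not hold for all tested genes. Alternatives were RLE and upper-quartile scaling, no filter and a stricter one (1 CPM in 5 libraries), DESeq2 1.42.0, limma voom with sample weights, edgeR's robust prior, a fit of all 20 libraries, 1 surrogate variable (sva 3.50.0), the replicate number as a block, an adjusted p of 0.1, an absolute log2 fold change of at least 1, and leaving out each library in turn. Further alternatives, chosen after the data were seen, were removal of each library's trend with GC content and gene length (splines of 4 degrees of freedom, Biostrings 2.70.1), the ribosomal RNA gene Rn18s left out, the epididymis marker level as a covariate, and the omission of liver WT 1 and WT 3 or of 4 eWAT libraries high in testis markers. The transcript reference at hand is of GRCm38 while the authors used GRCm39. Length and GC content were found for 99.9% of tested genes. A planned two-sided test of changed genes by distance from Insr was replaced by a one-sided test by gene order, at an unadjusted p under 0.05.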

Results

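Messenger RNA was sequenced from the liver and the epididymal white adipose tissue (eWAT, the fat depot attached to the epididymis) of 2-month-old male mice. The mice were wild type (WT) or carried IR 4A, a form of the insulin receptor altered in the motif that binds MAD2, a spindle checkpoint protein that takes part in removing the receptor from the cell surface. Each of the 4 groups (liver WT, liver IR 4A, eWAT WT, eWAT IR 4A) had 5 libraries, 20 in total. Total estimated counts ran from 17989420 to 24238359 per liver library and from 13651874 to 21615358 per eWAT library. In eWAT the totals were lower in IR 4A, with 14819719 ± 831535 counts (SD, n = 5) against 18518422 ± 2343709 in WT (two-sided exact permutation test, p = 0.00794, adjusted p = 0.0317 over 4 measures). In liver more genes were detected in IR 4A, 15138 ± 92.6 against 14908 ± 94.3 (exact permutation p = 0.00794, adjusted p = 0.0317). Neither difference passed when medians were permuted in place of means (exact permutation adjusted p = 0.19 for both). That alternative could not decide, since the groups did not overlap in either measure. The resulting exact permutation p of medians, 0.0476, is the smallest that 5 against 5 libraries allow. A single measure of 4 cannot pass from there after adjustment. The labels do not number the animals, so p-values measure the spread between these libraries.

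The receptor gene itself was read first, followed by its signalling partners. Insr (ENSMUSG00000005534) stood at 157 ± 7.87 CPM (scaled counts, SD, n = 5) in WT liver and at 168 ± 10.1 CPM in IR 4A liver, a log2 fold change of 0.09 (SE 0.07). It did not pass (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.506). In eWAT it stood at 158 ± 33.0 CPM in WT and 128 ± 29.6 CPM in IR 4A, a log2 fold change of -0.31 (SE 0.19, edgeR adjusted p = 0.445). The eWAT value passed with 1 surrogate variable in the model (log2 fold change -0.42, adjusted p = 0.0231, where the adjusted p ran from 0.0231 to 0.892 over 23 alternatives). As IR 4A changes residues of the protein, the level of Insr mRNA does not check the genotype labels. Igf1r, the receptor for insulin-like growth factor 1, had log2 fold changes of 0.24 (SE 0.23) in liver and 0.55 (SE 0.28) in eWAT. The adaptor genes Irs1 and Irs2 had 0.05 and -0.02 in liver and -0.62 and -0.33 in eWAT. Mad2l1, which encodes MAD2, and Mad2l1bp, which encodes its binding partner p31comet, had -0.05 and 0.00 in liver and -0.14 and 0.12 in eWAT. None of these 5 genes passed in either tissue (edgeR adjusted p from 0.363 to 0.999). Bub1b, which encodes the checkpoint protein BUBR1, had -0.62 in eWAT (SE 0.40, edgeR adjusted p = 0.466).

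The first comparison asked which liver transcripts differ between IR 4A and WT. By camera with its preset correlation, 16 gene lists changed in liver. That number was not beyond chance, as 27 of 100 splits of the libraries, the real one included, called as many (highest other 26). No liver list passed by its level, the mean log2 CPM of its genes. The exact permutation adjusted p was 0.0893 for the lipogenesis, glycolysis, glycogen and growth hormone lists, 0.143 for the circadian list, 0.179 for immediate early genes and 0.375 for the other 10 lists called. By camera, genes of de novo lipogenesis and of carbohydrate metabolism rose as groups in IR 4A liver. Other fat lists were not called, with camera adjusted p = 0.746 for fatty acid oxidation, 0.769 for lipid droplets and 0.681 for fatty acid uptake and triglyceride synthesis. Of the 26 tested genes of de novo lipogenesis, 22 had a positive log2 fold change (median 0.29, camera adjusted p = 0.000328, adjusted p = 0.661 with an estimated correlation). Scd1, a desaturase that makes monounsaturated fatty acids, stood at 2351 ± 1140 CPM in WT and 5372 ± 1294 CPM in IR 4A (log2 fold change 1.19, SE 0.32, edgeR adjusted p = 0.133). Fasn, the fatty acid synthase, stood at 181 ± 46.6 and 262 ± 18.5 CPM (0.53, SE 0.16, edgeR adjusted p = 0.153). Srebf1, a transcription factor of lipogenesis, had 0.66 (SE 0.26, edgeR adjusted p = 0.223). Glycolysis and glucose uptake genes rose, 19 of 25 being positive (median 0.16, camera adjusted p = 0.0316, adjusted p = 0.661 with an estimated correlation). Glycogen metabolism genes rose, 14 of 17 being positive (median 0.23, camera adjusted p = 0.0215, adjusted p = 0.661 with an estimated correlation). Their leading members were Gbe1, the branching enzyme, at 0.50, and Gys2, the liver glycogen synthase, at 0.55. Citric acid cycle genes rose, 18 of 23 being positive (median 0.09, camera adjusted p = 0.0495, adjusted p = 0.81 with an estimated correlation), with Idh2, the mitochondrial isocitrate dehydrogenase, at 0.38. This call was kept in 6 of 12 other settings.

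Further liver groups rose in IR 4A by camera. Circadian clock and output genes were positive in 18 of 22 (median 0.34, camera adjusted p = 0.000316, adjusted p = 0.661 with an estimated correlation), with the clock transcription factors Rora at 0.37 and Bhlhe40 at 0.57 and the period gene Per3 at 0.77. Immediate early genes were positive in 15 of 21 (median 0.43, camera adjusted p = 0.000831, adjusted p = 0.661 with an estimated correlation), with the transcription factors Myc at 1.56 (SE 0.44) and Jun at 0.92 and the antiproliferative gene Btg2 at 0.85. Extracellular matrix genes were positive in 35 of 42 (median 0.39, camera adjusted p = 7.57e-05, adjusted p = 0.713 with an estimated correlation). The collagen genes Col6a3 (0.82, SE 0.18) and Col14a1 (0.78, SE 0.18) were higher in every IR 4A library than in every WT library. Genes of the growth hormone and IGF axis were positive in 13 of 20 (median 0.12, camera adjusted p = 0.0215, adjusted p = 0.661 with an estimated correlation). Their leading members were Cish, a feedback inhibitor of cytokine receptors, at 1.95 (SE 0.44), and the IGF-binding proteins Igfbp5 at 1.38 and Igfbp3 at 1.13. This was the one list also called by fry, a self-contained test of whether its genes move one way (adjusted p = 0.0087), while its camera call was kept in 8 of 12 other settings. Xenobiotic metabolism genes were positive in 24 of 34 (median 0.23, camera adjusted p = 0.0293, adjusted p = 0.81 with an estimated correlation), although the glutathione transferases Gstm3 and Gstp1 had 0.92 and -0.42. Markers of stellate cells (8 of 10 positive, median 0.32, camera adjusted p = 0.0193), of dendritic cells (8 of 8, median 0.36, 0.0126) and of periportal hepatocytes (10 of 12, median 0.25, 0.0447) rose too. With an estimated correlation their adjusted p was 0.661, 0.661 and 0.81. The matrix protein genes Reln and Dcn of the stellate list had 0.69 and 0.40, the transcription factor Zbtb46 of the dendritic list 0.60 and the aldehyde dehydrogenase Aldh1b1 of the periportal list 0.79.

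Among the groups that fell by camera in IR 4A liver, the acute phase response had the largest median change. Of its 32 genes 29 were negative (median -0.89, camera adjusted p = 1.99e-07, adjusted p = 0.661 with an estimated correlation). Saa2, a serum amyloid A protein, stood at 2645 ± 3746 CPM in WT and 110 ± 82.6 CPM in IR 4A (log2 fold change -4.58, SE 1.37, edgeR adjusted p = 0.154). Lcn2, an iron-siderophore binder, and Apcs, serum amyloid P, had -4.55 and -2.99. This group followed 2 WT libraries: Saa2 reached 8493 CPM in WT 1 and 4353 CPM in WT 3 and lay between 45.5 and 183 CPM in the other 3 WT libraries, against 10.7 to 194 CPM in IR 4A. Genes of the integrated stress and unfolded protein response were negative in 27 of 33 (median -0.33, camera adjusted p = 2.11e-05, adjusted p = 0.661 with an estimated correlation). Atf5, a stress-induced transcription factor, stood at 160 ± 77.5 and 78.2 ± 9.06 CPM (-1.03, SE 0.26, edgeR adjusted p = 0.127). The endoplasmic reticulum genes Sdf2l1 and Hyou1 had -0.93 and -0.99. All 3 were highest in WT 1, and without WT 1 and WT 3 they had -0.45, -0.55 and -0.73 and the list a median of -0.16 (camera adjusted p = 0.00414). Genes known to be higher in male than in female liver were negative in 23 of 30 (median -0.19, camera adjusted p = 0.00187, adjusted p = 0.661 with an estimated correlation). Elovl3, a fatty acid elongase, had -0.998 and the major urinary protein gene Mup11, whose reads near-identical family members can share, had -0.86. Spindle checkpoint and receptor endocytosis genes were negative in 21 of 25 (median -0.11, camera adjusted p = 0.0495, adjusted p = 0.661 with an estimated correlation), a call kept in 2 of 12 other settings. The clathrin adaptor gene Ap2a2 had -0.29 and Ide, the insulin-degrading enzyme, 0.55.

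Unlike the lipogenesis and glycolysis lists above, the lists for insulin signalling, insulin-repressed FoxO1 targets and gluconeogenesis were not called in liver. Insulin signalling genes had a median of -0.00 over 33 genes (camera adjusted p = 0.769), FoxO1 targets that insulin represses 0.05 over 24 (0.891), and genes of gluconeogenesis and the glucagon response 0.13 over 35 (0.262). The gluconeogenic genes Pck1 and G6pc had -0.03 (SE 0.13) and -0.39 (SE 0.42), and Igfbp1, an IGF-binding protein gene, had -0.31 (SE 0.21). Genes higher in female liver went both ways (8 of 13 positive, camera adjusted p = 0.681). Cyp2c40, of a P450 family whose members can share reads, stood at 10.5 ± 5.45 CPM in WT and 2.00 ± 0.364 CPM in IR 4A (-2.39, edgeR adjusted p = 0.0622), and the monooxygenase gene Fmo2 at 9.99 ± 2.40 and 23.7 ± 6.399 CPM (1.25, edgeR adjusted p = 0.0727). Cholesterol synthesis and uptake genes had a median of -0.28 (camera adjusted p = 0.0937).

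Of the liver genes named so far, none passed on its own (edgeR adjusted p from 0.0622 to 0.999). Over all genes, 0 were higher and 1 was lower in IR 4A among 12421 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The lower gene was Erdr1 (ENSMUSG00000095562), at 23.0 ± 3.81 CPM in WT (17.5 to 27.1 over 5 libraries) and 4.09 ± 2.12 CPM in IR 4A (2.21 to 7.72), a log2 fold change of -2.48 (SE 0.27, edgeR adjusted p = 0.00939). At an unadjusted p under 0.05 there were 2246 genes, 1068 higher and 1178 lower, where 621 would be expected on average by chance. Of 100 splits of the libraries, the real one included, 2 gave as many (highest other 2750), a number not adjusted over the counts compared. Of all tested genes 3.51% had groups that did not overlap, against 0.794% by chance. DESeq2 on the same counts gave 182 higher and 225 lower genes, and limma voom with sample weights gave 2 and 2. Within the lists, 0 members passed over all genes tested. Adjusted over the list alone, 7 higher and 2 lower lipogenesis genes, 1 higher and 17 lower acute phase genes, 1 higher and 9 lower stress response genes, 7 higher immediate early genes, 5 higher matrix genes and 5 higher growth hormone and IGF axis genes passed. Simulated libraries had the same depth and spread, with genes drawn independently and only those of higher count changed. In these the test recovered 28.4% of genes changed by a log2 of 0.5 and 83.6% of those changed by 1.

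The liver counts depended on single libraries. They became 80 higher and 63 lower without IR 4A 1 and 1 and 3 without WT 4. There was 1 higher gene without WT 3 and without IR 4A 5, 2 were lower without WT 1, and 0 were lower without IR 4A 2, 3 or 4, without both WT 1 and WT 3, or with 1 surrogate variable. List calls ended, with camera adjusted p up to 0.164 for spindle checkpoint and endocytosis (without WT 1, WT 3, WT 4 or any IR 4A library), 0.0561 for glycolysis (without WT 1 or WT 3), 0.239 for xenobiotic metabolism (without WT 1, WT 3 or IR 4A 5), 0.0539 for the growth hormone axis (without WT 3), 0.215 for the citric acid cycle (without WT 1, WT 3, WT 4 or IR 4A 1, 2, 4 or 5), 0.239 for periportal markers (without WT 1, WT 3 or IR 4A 3 or 4) and 0.0525 for stellate markers (without WT 2, WT 3, WT 4 or IR 4A 4). In all, 9 lists were called without WT 3, against 16 with all libraries. Without WT 1 and WT 3 together the lipogenesis call ended as well (camera adjusted p = 0.0589, from 1.23e-05 to 0.0589 over alternatives), as did that for the acute phase response (0.076, from 4.17e-10 to 0.076) and those for the glycogen and dendritic lists. The lists named before it lost their calls there too, apart from stellate markers. With these libraries out, the circadian median was 0.17, and Srebf1 had 0.40, Gys2 0.19, Per3 0.51, Gstm3 0.55, Saa2 -0.21 and Apcs -0.07. Lcn2 turned sign there, to 0.047, and the xenobiotic list turned its direction by camera. Medians also moved by over 1.5 times without WT 1 (lipogenesis 0.16, acute phase -0.45, stress response -0.20, xenobiotic metabolism 0.15, growth hormone axis 0.075), WT 3 (periportal 0.17), WT 4 (spindle checkpoint -0.05, citric acid cycle 0.16), WT 5 (male-biased -0.12), IR 4A 1 (growth hormone axis 0.05, dendritic 0.54) or IR 4A 3 (matrix 0.26, growth hormone axis 0.065). Among other settings, 1 surrogate variable ended the calls for the matrix, male-biased, growth hormone, glycolysis, spindle, periportal, stellate and dendritic lists. The fit of all 20 libraries ended those for the male-biased, xenobiotic, citric acid, spindle, periportal and stellate lists. The growth hormone call also ended with the stricter filter and with voom, and the periportal call with the robust prior.

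**Figure D1:**
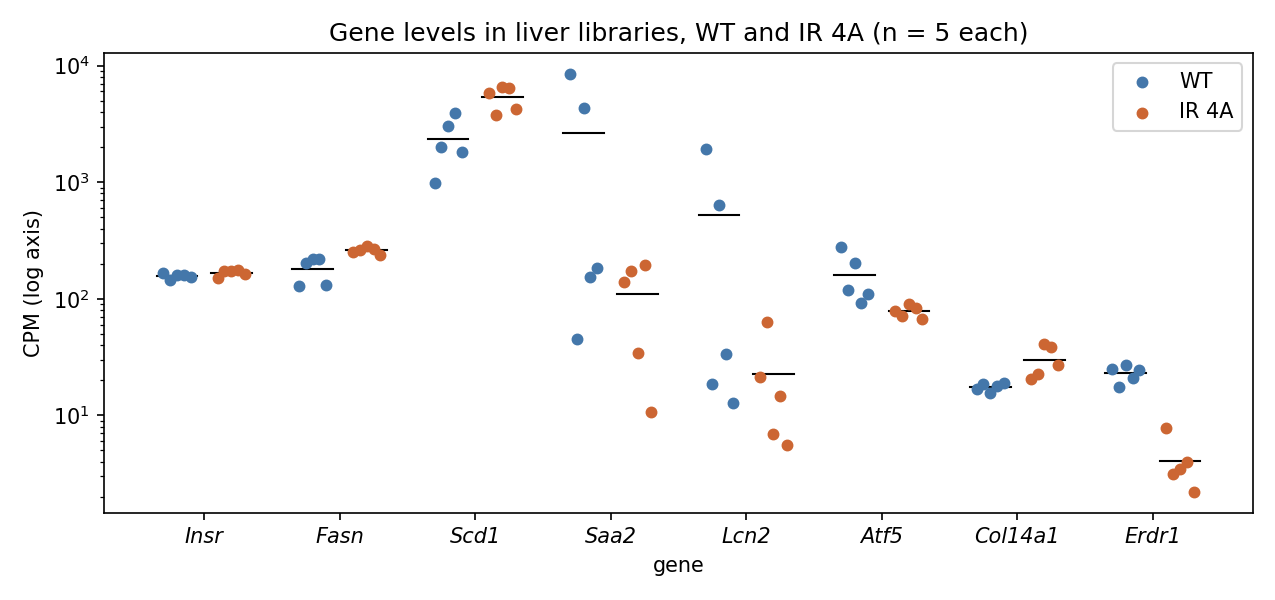
CPM (log axis) of 8 genes in the 5 WT (blue) and 5 IR 4A (orange) liver libraries, with each group's mean as a line. Fasn, Atf5, Col14a1 and Erdr1 show no overlap between the groups, while Saa2 and Lcn2 are high in WT 1 and WT 3 alone.

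The second comparison asked which eWAT transcripts differ between IR 4A and WT. By camera with its preset correlation 25 lists changed, a number not beyond chance, as 40 of 100 splits of the libraries, the real one included, called as many (highest other 34). Genes of the connective tissue and of some immune cell types fell as groups in IR 4A eWAT. Of 45 tested extracellular matrix genes 43 were negative (median -1.28, camera adjusted p = 8.65e-23, adjusted p = 0.383 with an estimated correlation). The mean level of these genes was 7.09 ± 0.52 log2 CPM in WT and 5.86 ± 0.69 in IR 4A (SD, n = 5), each IR 4A library lying below each WT library (exact permutation p = 0.00794, adjusted p = 0.0459 over the lists tested). Fbn1, which encodes fibrillin 1, stood at 225 ± 182 CPM in WT and 33.3 ± 17.7 CPM in IR 4A (log2 fold change -2.76, SE 0.57, edgeR adjusted p = 0.164). Col14a1 had -1.51 (SE 0.29) and Timp2, an inhibitor of matrix metalloproteinases, -1.43 (SE 0.29), both lower in every IR 4A library than in every WT library. Adipocyte progenitor markers were negative in 11 of 12 (median -0.43, camera adjusted p = 0.000804, adjusted p = 0.383 with an estimated correlation), with the proteoglycan gene Dcn at 725 ± 313 and 287 ± 109 CPM (-1.34, SE 0.34). Mesothelium markers fell, 8 of 12 being negative (median -1.17, camera adjusted p = 0.00359, adjusted p = 0.383 with an estimated correlation). Bnc1, a zinc finger protein of that list, stood at 5.11 ± 1.61 and 1.25 ± 0.527 CPM (-2.02, SE 0.36), while the keratin gene Krt18, which other epithelia also express, had 0.65.

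Macrophage markers were negative in 13 of 14 (median -1.05, camera adjusted p = 1.96e-08, adjusted p = 0.451 with an estimated correlation). Adgre1, which encodes F4/80, stood at 15.6 ± 7.10 CPM in WT and 5.67 ± 1.8 CPM in IR 4A (-1.46, SE 0.34, edgeR adjusted p = 0.173). Mrc1, the mannose receptor, and Lyz2, a lysozyme, had -1.56 and -1.67. The list written for Kupffer cells of the liver, which shares Adgre1 and complement genes with the macrophage list, was negative in 9 of 9 (median -1.46, camera adjusted p = 3.52e-09, adjusted p = 0.383 with an estimated correlation). Markers of B cells (9 of 9 negative, median -1.49, camera adjusted p = 7.14e-05) and of mast cells (6 of 6, median -2.67, 0.000746) fell, each with an adjusted p of 0.383 with an estimated correlation. Cpa3, a mast cell protease, had -3.10, at group means under 3 CPM. The lists written for liver sinusoidal endothelium and stellate cells also fell (medians -0.50 and -0.48, camera adjusted p = 0.0132 and 0.0123, adjusted p = 0.445 and 0.383 with an estimated correlation), led by Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, at -2.53, and by Dcn. The level of the progenitor, mesothelium, macrophage, Kupffer, B cell, mast cell, sinusoidal and stellate lists was lower in every IR 4A library than in every WT library (exact permutation p = 0.00794, adjusted p = 0.0459 for each). This p is the smallest that the splits allow, so the adjusted p depends on how many lists tie at it. Some of these lists share members, and they are not separate passes. Dilution of adipose RNA by RNA of the epididymis or testis was not tested for these lists. Their levels differed by -0.46 (stellate) to -1.68 (mast cell), around the -0.98 of adipocyte markers. They therefore do not show a loss of these cell types from the fat. The B cell and mast cell levels in IR 4A were also low, 0.23 and 0.35 log2 CPM. Markers of vascular endothelium (12 of 12 negative, median -0.89, camera adjusted p = 0.00015) and of dendritic cells (10 of 10, median -0.58, 0.00438) fell as well, with adjusted p = 0.714 and 0.707 with an estimated correlation, and Vwf, a gene of endothelial cells, had -1.20. Their levels did not pass (exact permutation adjusted p = 0.223 and 0.161). Markers of lipid-associated and inflammatory macrophages did not pass and went both ways, 5 of 11 being positive (median -0.24, camera adjusted p = 0.938). Markers of T and NK cells did not pass (median 0.09, camera adjusted p = 0.995).

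Genes of the fat cell were lower too by camera, but not by the level of any list. Adipocyte markers were negative in 13 of 13 (median -0.84, camera adjusted p = 0.000393, adjusted p = 0.714 with an estimated correlation), but their level overlapped between 8.53 ± 0.68 log2 CPM in WT and 7.55 ± 1.13 in IR 4A (exact permutation p = 0.183, adjusted p = 0.306). Adipoq, the adiponectin gene, stood at 1078 ± 624 and 575 ± 362 CPM (-0.91, SE 0.54, edgeR adjusted p = 0.435). Lep, the leptin gene, stood at 213 ± 125 and 114 ± 82.9 CPM (-0.91, SE 0.62, edgeR adjusted p = 0.493). Pparg, the adipogenic nuclear receptor, had -1.04, Acvr1c, an activin receptor, -1.19 and the glucose transporter gene Slc2a4 -0.36. Adipokines (19 of 21 negative, median -0.69, camera adjusted p = 0.000488), lipid droplet and lipolysis genes (24 of 28, median -0.66, 0.000746), fatty acid oxidation genes (27 of 33, median -0.39, 0.00723) and citric acid cycle genes (22 of 23, median -0.21, 0.0144) fell. With an estimated correlation their adjusted p was 0.714, 0.714, 0.776 and 0.844, and by level 0.271, 0.306, 0.169 and 0.317 (exact permutation). Abhd5, a coactivator of the adipose triglyceride lipase, had -0.65, and Hadha, of mitochondrial beta-oxidation, -0.39. Insulin signalling genes were negative in 26 of 33 (median -0.30, camera adjusted p = 0.0123, adjusted p = 0.752 with an estimated correlation, exact permutation adjusted p = 0.197 by level), with the phosphoinositide 3-kinase genes Pik3cb at -0.67 and Pik3r1 at -0.83. The growth hormone and IGF axis (15 of 19 negative, median -0.40, camera adjusted p = 0.00257), the acute phase list (21 of 24, median -0.95, 0.000555), interferon response genes (38 of 40, median -0.46, 6.77e-05) and cell cycle genes (40 of 45, median -0.45, 0.0365) fell, with adjusted p = 0.714, 0.714, 0.714 and 0.847 with an estimated correlation. By level the exact permutation adjusted p was 0.251, 0.146, 0.245 and 0.392. The growth factor genes Igf1 and Igf2 had -1.16 and -0.93, the complement gene C3 -2.04, the haptoglobin gene Hp -1.38 and the interferon-induced Ifit1 -0.73. De novo lipogenesis genes did not pass in eWAT (median -0.41, camera adjusted p = 0.28), where Fasn had -0.65 (SE 0.53) and Srebf1 -0.03 (SE 0.23). WT 4 had the highest values of Adipoq, Lep, Pparg and Fasn, and without it these genes had -0.48, -0.52, -0.64 and -0.04 and Slc2a4 0.09.

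The groups that rose by camera in IR 4A eWAT were 4, and none passed by level (exact permutation adjusted p = 0.0636 for cholesterol genes, 0.306 for stress response genes, 0.0636 for epididymis markers and 0.0636 for the cholangiocyte list). Cholesterol synthesis and uptake genes were positive in 21 of 26 (median 0.31, camera adjusted p = 4.12e-07, adjusted p = 0.383 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, stood at 65.6 ± 9.67 CPM in WT and 91.7 ± 7.60 CPM in IR 4A (0.48, SE 0.11). The sterol reductase Tm7sf2 had 0.69 and Insig1, a regulator of sterol sensing, 0.35. Integrated stress and unfolded protein response genes were positive in 24 of 34 (median 0.13, camera adjusted p = 0.00257, adjusted p = 0.707 with an estimated correlation), with the mitochondrial serine enzyme gene Shmt2 at 0.52. Epididymis markers were positive in 16 of 16 (median 0.70, camera adjusted p = 6.19e-08, adjusted p = 0.383 with an estimated correlation). Crisp1, a protein secreted onto sperm, stood at 2147 ± 570 and 3602 ± 622 CPM (0.75, SE 0.22). The list written for cholangiocytes was positive in 10 of 10 (median 0.39, camera adjusted p = 0.000339, adjusted p = 0.451 with an estimated correlation), led by the epithelial adhesion genes Cldn7 at 0.69 and Epcam at 0.41.

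RNA of the adjoining organ was present in each eWAT library. The 16 epididymis genes took between 2.6% and 5.38% of all counts in 9 libraries and 0.52% in WT 4. Their level was 9.85 to 10.41 log2 CPM in IR 4A and 9.42 to 9.91 in 4 WT libraries, with WT 4 at 2.89 (exact permutation p = 0.0159, adjusted p = 0.0636). Testis and sperm markers had a level of 6.43 to 7.86 in WT 1, WT 2, IR 4A 3 and IR 4A 4 and did not differ between the genotypes (exact permutation p = 0.746). In those IR 4A libraries the matrix level was 4.98 and 5.32, the lowest of the 10.

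Of the eWAT genes named so far, none passed on its own (edgeR adjusted p from 0.16 to 0.948). Over all genes, 0 were higher and 2 were lower in IR 4A among 16476 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Itgbl1 (ENSMUSG00000032925), a secreted protein related to integrin beta chains, stood at 19.4 ± 1.38 CPM in WT and 7.25 ± 1.36 CPM in IR 4A (log2 fold change -1.42, SE 0.15, edgeR adjusted p = 0.044). Tnmd (ENSMUSG00000031250), tenomodulin, stood at 1.39 ± 0.295 and 0.0676 ± 0.0490 CPM (-4.23, SE 0.48, edgeR adjusted p = 0.044). Its mean over the 10 libraries lay under the level set for named genes, and it was added after its values were seen. At an unadjusted p under 0.05 there were 2615 genes, 1092 higher and 1523 lower, where 824 would be expected on average by chance. Chance is not excluded for that count, as 7 of 100 splits of the libraries, the real one included, gave as many (highest other 5441). Of tested genes 5.74% had groups that did not overlap, against 0.794% on average by chance, a share that was not counted over splits. DESeq2 gave 487 higher and 634 lower genes, and limma voom with sample weights 18 and 60. Within the lists 0 members passed over all genes tested. Adjusted over the list alone, 34 lower matrix genes, 12 lower macrophage genes, 9 lower Kupffer genes, 8 lower and 2 higher mesothelium genes, 5 lower progenitor genes, 4 lower mast cell genes, 5 higher cholesterol genes and 3 higher epididymis genes passed. Simulated libraries had this depth and spread, with genes drawn independently and only those of higher count changed. The test recovered 0% of genes changed by a log2 of 0.5, 19.4% of those changed by 1 and 60.9% of those changed by 2.

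The 2 lower eWAT genes did not pass without any 1 of 9 libraries, and without IR 4A 3 there were 2 higher and 4 lower genes. With 1 surrogate variable there were 187 higher and 1718 lower genes, and 0 of either with the epididymis level as a covariate or without the 4 libraries highest in testis markers. Itgbl1 and Tnmd had -1.40 and -4.37 with the covariate (edgeR adjusted p = 0.122 for both). With that covariate 15 lists were called, among them the matrix list (median -0.83, camera adjusted p = 6.85e-20, at most 1.01e-18 over alternatives), and the calls ended for insulin signalling, fatty acid oxidation, lipid droplet, growth hormone axis, acute phase, interferon, citric acid cycle, adipokine, adipocyte, dendritic and epididymis lists. Leaving out single libraries ended the calls for insulin signalling (WT 4, WT 5, IR 4A 3 or 4, camera adjusted p up to 0.157), fatty acid oxidation (WT 4 or IR 4A 3, 0.252), the citric acid cycle (WT 4, IR 4A 3 or 4, 0.612), the cell cycle (WT 1, WT 2, WT 3 or IR 4A 2, 3 or 5, 0.419), sinusoidal markers (WT 3, 0.0519) and, without WT 4, lipid droplet genes (0.0557), the acute phase list (0.0758) and dendritic markers (0.0578). Without WT 4 medians that moved by over 1.5 times were -0.68 for macrophages, -0.46 for adipocytes, -0.31 for adipokines, -0.34 for lipid droplets, -0.16 for fatty acid oxidation, -0.09 for the citric acid cycle, -0.13 for insulin signalling, -0.26 for the growth hormone axis, -0.25 for the acute phase, -0.25 for interferon, -0.35 for dendritic cells, 0.23 for cholangiocytes and 0.08 for the stress response. The cell cycle median was -0.08 without WT 2, that of insulin signalling -0.18 without WT 2 and -0.19 without IR 4A 3, that of the citric acid cycle -0.14 without IR 4A 4, and that of the stress response 0.19 without WT 5 and 0.08 without IR 4A 2. The fit of all 20 libraries ended the calls for mesothelium, mast cell, cell cycle and epididymis lists, and 1 surrogate variable that for the cell cycle. Voom ended those for insulin signalling, fatty acid oxidation, lipid droplets and the citric acid cycle, and the GC and length correction that for insulin signalling. Without the testis-high libraries the stress response, stellate, cell cycle and citric acid calls ended.

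**Figure D2:**
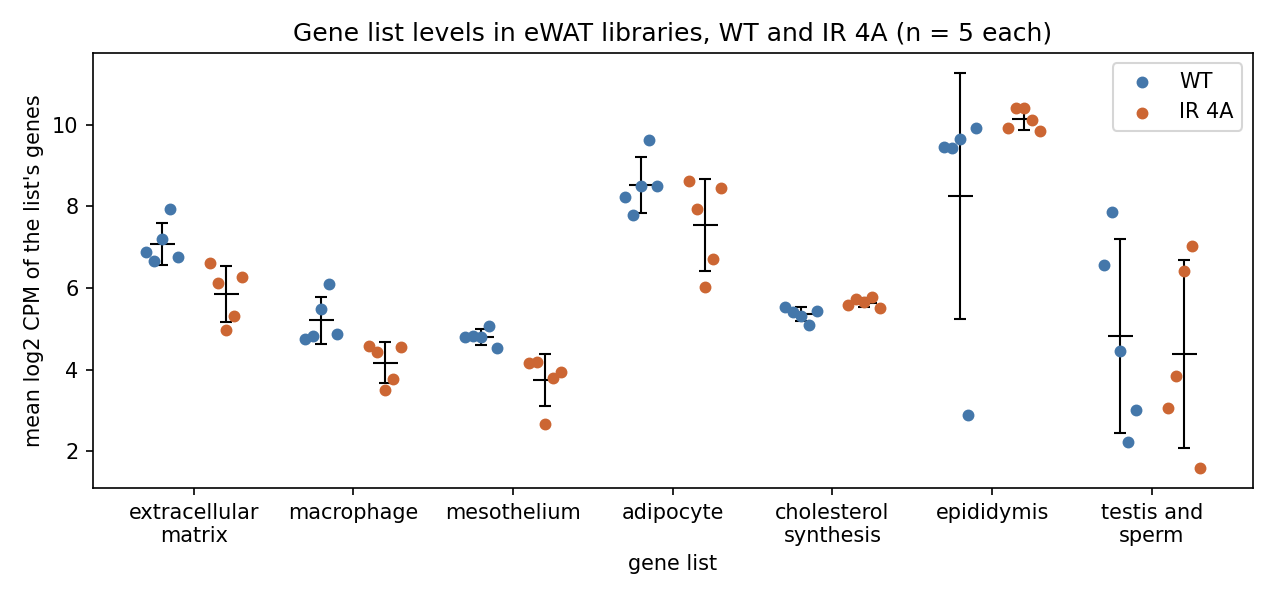
Mean log2 CPM of 7 gene lists in the 5 WT (blue) and 5 IR 4A (orange) eWAT libraries, with the group mean and SD as bars. The matrix, macrophage and mesothelium levels of the groups do not overlap, adipocyte levels do, and 1 WT library (WT 4) lies at 2.89 for epididymis markers.

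The third comparison asked whether IR 4A changed the same genes in both tissues. The difference between the eWAT and the liver fold change was tested over all 20 libraries for 14695 genes. It was larger in eWAT for 108 genes and smaller for 246 (edgeR quasi-likelihood test of the interaction, Benjamini-Hochberg adjusted p under 0.05). The fit gave each gene 1 dispersion for both tissues, although the spread was larger in eWAT than in liver. Within eWAT the same fit called 76 higher and 219 lower genes in IR 4A, where the eWAT libraries alone gave 0 and 2. The spread of eWAT may thus be understated in the interaction test. Of 45 matrix genes, 12 passed the threshold over all genes and 33 when adjusted over the list alone. Their median difference was -1.68, with the smallest camera adjusted p of the lists (1.86e-20, 0.351 with an estimated correlation). The share past the threshold was similar in the Kupffer (3 of 11) and stellate (3 of 10) lists. Genes were named here if their mean was at least 1 CPM in each tissue, scaled over all 20 libraries, and their symbol was informative. The 5 smallest differences among these began with Ntrk2, a neurotrophin receptor, at -4.89 (SE 0.73, edgeR adjusted p = 0.0141; 3.66 in liver and -1.19 in eWAT), Lyve1 at -3.89 (SE 0.73, edgeR adjusted p = 0.0184) and Fbn1 at -3.14 (SE 0.68, edgeR adjusted p = 0.029). The others were Ighd, an immunoglobulin heavy chain gene, at -3.09 and Tmeff2, a membrane protein, at -2.92 (edgeR adjusted p = 0.0494 and 0.0166). Itgbl1, which was not tested in liver alone for its low counts there, had -3.66 (edgeR adjusted p = 0.0263). By the same rule the 5 largest were Nfkbie, an inhibitor of NF-kappa-B, at 1.802, AW549542 at 1.53, the endoplasmic reticulum genes Sec61g at 1.48 and Sdf2l1 at 1.43, and Mettl1, a transfer RNA methyltransferase, at 1.28 (edgeR adjusted p from 0.0306 to 0.0484).

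Among lists, 24 of 49 differed between the tissues with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.351). Stress and unfolded protein response genes had a median difference of 0.41 (camera adjusted p = 6.62e-07, adjusted p = 0.351 with an estimated correlation) and cholesterol genes 0.52 (7.68e-06 and 0.478), being lower in liver and higher in eWAT by their medians. Lipogenesis genes had -0.65 (0.00265 and 0.62), glycogen genes -0.65 (0.0118 and 0.62), macrophage markers -1.32 (5.58e-05 and 0.59) and the Kupffer list -2.15 (3.75e-06 and 0.457). The median difference over all genes was -0.12 with TMM scaling, -0.07 with RLE and -0.02 with upper-quartile scaling, and the counts were 161 larger and 180 smaller under RLE and 194 and 166 under upper-quartile scaling. Removing each library's GC and length trend gave 328 larger and 124 smaller, and the epididymis covariate 13 and 52. Without the 4 testis-high eWAT libraries there were 3 and 20, and without liver WT 1 and WT 3 there were 14 and 82. With the replicate number as a block there were 0 and 0, although no label says that a number marks the same animal.

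Leaving out single libraries gave 10 (liver IR 4A 4) to 297 (eWAT WT 5) larger and 60 (liver IR 4A 4) to 480 (liver IR 4A 1) smaller genes. Either count moved by over 1.5 times without any 1 of liver WT 1, WT 3, WT 4 and IR 4A 1 to 5, or of eWAT WT 1, WT 3, WT 5 and IR 4A 2 to 4, and without eWAT WT 4 the smaller count became 96. In simulated libraries the test recovered 3.5%, 39.6% and 90.2% of differences of 0.5, 1 and 2 on the log2 scale. No gene passed in both tissues (0 of 11969 tested in both, edgeR), where DESeq2 gave 44. The edgeR count could not be above 0, as 1 of these genes passed in liver and 0 in eWAT, so it does not answer the question. At an unadjusted p under 0.05 in both there were 405 genes, 94 with the same and 311 with opposite sign, where 373.7 would be expected if the tissues were independent. Across genes, which are not independent replicates, the fold changes of the tissues had a correlation of -0.191.

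**Figure D3:**
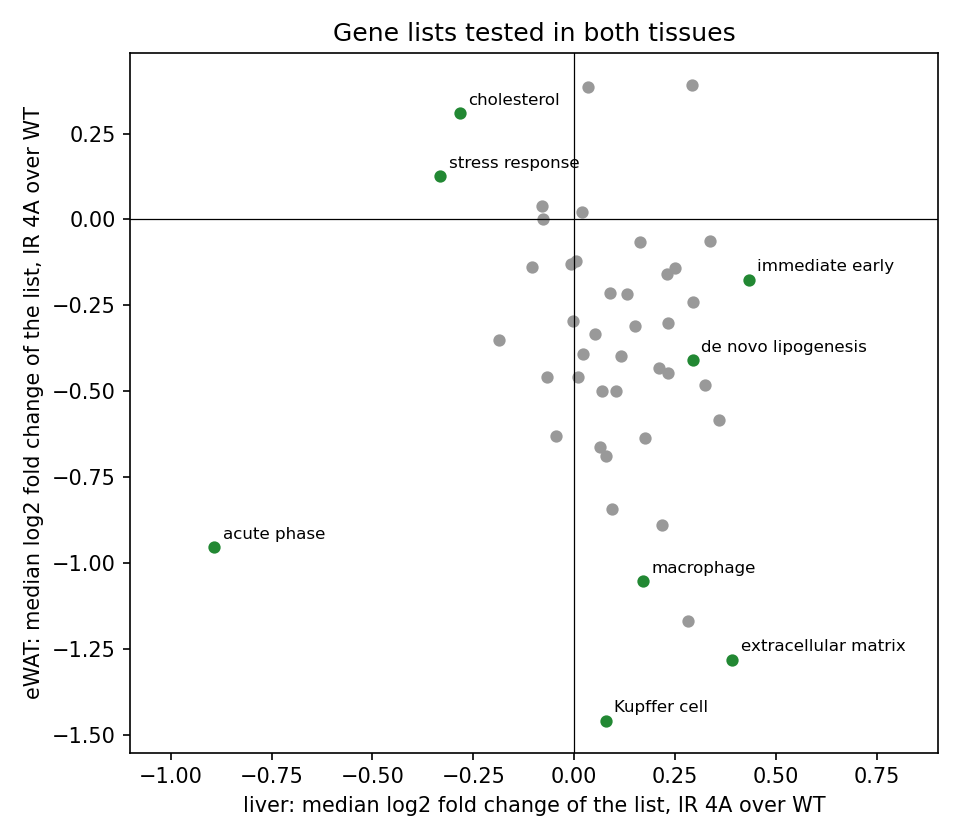
Median log2 fold change (IR 4A over WT) of each gene list in liver (horizontal axis) and eWAT (vertical axis), 1 point per list tested in both tissues, green where named. The matrix list lies at 0.39 in liver and -1.28 in eWAT and the stress response list at -0.33 and 0.13.

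The authors' deposited table of their own DESeq2 comparison listed 154 higher and 176 lower genes in liver and 180 higher and 323 lower genes in eWAT at an adjusted p under 0.05. Of the liver genes 307 were tested here, 306 with the same direction, 290 at an unadjusted p under 0.05 and 1 past the edgeR threshold. Of the eWAT genes 473 were tested, 471 with the same direction, 443 at an unadjusted p under 0.05 and 1 past the threshold. In the authors' deposited table Scd1 had an adjusted p of 0.00168, Fbn1 of 0.000343 and Itgbl1 of 2.56e-10 (DESeq2). Fasn and Srebf1 in liver had 0.449 and 0.388 there, and Tnmd in eWAT was given no adjusted p. Igf2 in eWAT had a log2 fold change of -0.181 (DESeq2 adjusted p = 0.771).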

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

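The tests in this part were all planned, apart from the marker genes of epididymis, which were picked as the most abundant after their values were seen. In 294 sets of 5 libraries (measures, list levels and named genes) 33 had 1 library far from the other 4, with a gap above 0.71 of the range, a limit that chance passes in about 1 of 20 sets. Of these, 20 were eWAT WT 4.

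WT 4 was the eWAT library poorest in epididymis markers (level 2.89, other WT 9.42 to 9.91) and in the cholangiocyte list (3.63, others 4.57 to 4.91), and rich in genes of fat and its stroma. Its levels were 6.25 for insulin signalling (5.78 to 5.9), 6.85 for lipid droplet genes (5.61 to 5.95) and 7.65 for the citric acid cycle (6.85 to 7.05). In CPM it held Adipoq at 2173 (597 to 899), Fasn at 2959 (627 to 1007), Pck1 at 2314 (683 to 1018), Pparg at 196 (56.7 to 82.6), Acvr1c at 176 (76.2 to 91.1) and Irs2 at 117 (46.8 to 66.7). Stromal genes of WT 4 were Dcn at 1266 CPM (517 to 718), Fbn1 at 543 (83.4 to 198), Timp2 at 484 (187 to 265), Vwf at 135 (44.4 to 68.8), Lyve1 at 60 (17.2 to 28.6), Bnc1 at 7.9 (3.82 to 4.91) and Cpa3 at 7.2 (0.679 to 1.84), and the growth factors Igf1 at 305 (127 to 178) and Igf2 at 26.2 (14.7 to 17.1). Elsewhere in eWAT, IR 4A 3 was low in the acute phase list (2.81, others 4.03 to 4.43) and mesothelium markers (2.66, 3.79 to 4.18) and IR 4A 1 was high in Mad2l1 (16.6 CPM, 9.59 to 11.4).

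Epididymis markers in WT 4 did not fall alike. Gpx5, a secreted peroxidase, stood at 10.2 CPM against 9418 to 18041 in the other 9 libraries, and Lcn8, a lipocalin, and Spag11b, a defensin-like gene, at 0.0503 CPM each against 1671 to 4550 and 2052 to 3778. Adam7, a sperm-associated membrane protein, kept 1187 CPM (4140 to 6817) and Crisp1 2929 CPM (1461 to 4311). In all, 13 of the 16 genes lay below the range of the other libraries and 3 within it. The eWAT table held all 16 genes and none is on another list; of the testis list it held 13 of 13, none on another list, and of the adipocyte list 13 of 13, of which 9 are on another list.

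In liver the ribosomal RNA gene Rn18s took 8.87% of the counts of WT 4 (other WT 0.519% to 1.11%). WT 1 was low in glycogen genes (3.82, others 4.26 to 4.39) and in the desaturase gene Fads1 (257 CPM, 334 to 346). WT 5 was high in male-biased genes (8.93, 8.43 to 8.55) and Mup11 (20504 CPM, 12699 to 14492) and low in Cish (2.39 CPM, 6.24 to 7.53). Among IR 4A libraries, IR 4A 1 was high in G6pc (348 CPM, 86.9 to 130) and Mad2l1bp (5.26, 2.9 to 3.26) and IR 4A 2 in Lcn2 (63.7, 5.59 to 21.2), and IR 4A 3 was low in Ide (128, 144 to 148).

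Of the named genes, 20 had an IR 4A change that differed between the tissues by the interaction test (edgeR quasi-likelihood, adjusted p under 0.05; eWAT minus liver, log2). The positive differences were Nfkbie 1.802, AW549542 1.53, Sec61g 1.48, Sdf2l1 1.43 and Mettl1 1.28. The negative ones were Ntrk2 -4.89, Lyve1 -3.89, Itgbl1 -3.66, Fbn1 -3.14, Ighd -3.09, Tmeff2 -2.92, Col6a3 -2.46, Col14a1 -2.31, Timp2 -2.04, Mrc1 -2.03, Fmo2 -1.81, Dcn -1.76, Igfbp3 -1.75, Reln -1.22 and Zbtb46 -1.18.

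By camera, 24 lists differed, none of them with an estimated correlation (smallest adjusted p = 0.351). The medians were positive for cholesterol (0.52) and stress response genes (0.41). They were negative for B cells (-2.68), the Kupffer list (-2.15), mesothelium (-1.69), matrix (-1.68), macrophages (-1.32), xenobiotic metabolism (-1.23), dendritic cells (-1.15), vascular endothelium (-1.096), adipokines (-0.93), female-biased genes (-0.92), adipocytes (-0.91), cell cycle (-0.86), stellate cells (-0.74), progenitors (-0.69), glycogen (-0.65), lipogenesis (-0.65), sinusoidal endothelium (-0.64), immediate early genes (-0.62), lipid droplets (-0.61), interferon response (-0.57), the growth hormone and IGF axis (-0.48) and the citric acid cycle (-0.41), where the median of all genes was -0.12.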

How the results depend on the processing

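Removal of the GC and length trend, omission of Rn18s, the epididymis covariate and the omissions of several libraries were chosen after the data were seen. The report counted 0 higher and 1 lower liver gene, 0 higher and 2 lower eWAT genes, and 108 larger and 246 smaller differences between tissues.

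DESeq2 gave 182 and 225 in liver, 487 and 634 in eWAT, 593 larger and 651 smaller differences, and 44 genes in both tissues. Limma voom with sample weights gave 2 and 2, 18 and 60, and 256 and 372. A fit of all 20 libraries gave 40 and 9 in liver and 76 and 219 in eWAT, and is not an alternative for the difference between tissues, which already uses them. With 1 surrogate variable there were 0 lower liver genes, 187 and 1718 eWAT genes, 172 and 694 differences and 8 liver lists against 16, and Insr in eWAT was -0.42 (adjusted p = 0.0231, from 0.0231 to 0.892 over alternatives). Upper-quartile scaling gave 1 lower eWAT gene and 194 larger differences, no filter 0 lower eWAT genes, and the stricter filter 1 lower eWAT gene and 210 larger differences. An adjusted p under 0.1 gave 13 and 5 genes in liver and 421 and 810 differences, and requiring an absolute log2 change of at least 1 gave 22 larger differences.

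With the GC and length trend removed there were 1 higher and 0 lower eWAT genes and 328 larger and 124 smaller differences. The epididymis covariate gave 0 lower eWAT genes, 13 and 52 differences and 15 eWAT lists against 25. Without the 4 testis-high eWAT libraries there were 0 lower eWAT genes and 3 and 20 differences, and without liver WT 1 and WT 3 there were 0 lower liver genes and 14 and 82 differences. A correlation estimated per list called 0 lists in either tissue, and fry 1 in liver and 0 in eWAT. Permuting medians left 0 technical measures past the threshold in each tissue, against 1, but with 5 libraries per group a single measure could not pass that way. At an adjusted p under 0.1 the authors' deposited table has 300 and 359 liver genes and 360 and 533 eWAT genes.

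Leaving out single libraries gave 0 to 80 higher and 0 to 63 lower liver genes (both highest without IR 4A 1), 0 to 2 higher and 0 to 4 lower eWAT genes (highest without IR 4A 3), 10 to 297 larger and 60 to 480 smaller differences, and 9 (without WT 3) to 22 liver lists. Insr in liver lay between 0.05 and 0.13 in every alternative.

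Some fold changes, most of them small, turned sign in some settings. In liver these were Irs1 at -0.074 (voom) and -0.10 (without WT 1 and WT 3), Irs2 at 0.014 (all 20 libraries) and 0.14 (surrogate variable), Pck1 at 0.003 and 0.074 (the same settings), Mad2l1 at 0.009 (voom) and 0.034 (surrogate variable), and Mad2l1bp at 0.003 (stricter filter), 0.029 (all 20 libraries) and 0.031 (surrogate variable). Without WT 1 and WT 3, Lcn2 was at 0.047 and the xenobiotic list changed its direction by camera, with a median of 0.073. In eWAT they were Mad2l1 at 0.076 with the GC and length trend removed and at 0.077 without the testis-high libraries, Mad2l1bp at -0.065 (voom), -0.014 (epididymis covariate) and -0.145 (without the testis-high libraries), and Srebf1 at 0.04 (upper quartile), 0.12 (voom) and 0.24 (epididymis covariate). With that covariate Fasn was at 0.10 and Slc2a4 at 0.19, the citric acid list turned its direction by camera with a median of -0.034, and the epididymis list stood at -0.13.

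With single libraries left out the ranges were -0.17 to 0.16 for Irs1, -0.17 to 0.092 for Irs2, -0.08 to 0.043 for Pck1, -0.16 to 0.12 for Mad2l1 and -0.20 to 0.19 for Mad2l1bp in liver, and -0.042 to 0.25 for Mad2l1bp, -0.15 to 0.19 for Srebf1 and -0.64 to 0.09 for Slc2a4 in eWAT.

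The replicate numbers were also fitted as a block. The labels do not say whether they pair the libraries. Same-numbered libraries had correlations of -0.072 to 0.077 in liver and -0.726 to 0.67 in eWAT. Between tissues these were -0.086 to 0.034 in WT and -0.164 to 0.069 in IR 4A. At most 1 of 5 correlated best with its own number. Such values show no pairing but cannot exclude it, since tissues of the same animal need not vary together. With the replicate block there were 2 higher liver genes, 0 lower eWAT genes, and 0 larger and 0 smaller differences, Mad2l1bp in liver was at 0.012 and Srebf1 in eWAT at 0.034.

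Of 46 named liver genes, DESeq2 made 27 stronger and left 19 the same, and RLE, upper-quartile scaling, no filter, the robust prior, Rn18s left out and the GC and length correction left all 46 the same. Of 47 in eWAT, DESeq2 made 26 and the surrogate variable 33 stronger, and RLE and the robust prior left all 47 the same. Of the 16 liver lists, 9 were weaker without WT 1 and WT 3 and 8 with a surrogate variable; of the 25 eWAT lists, 9 were weaker with the epididymis covariate and 4 without the testis-high libraries.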

Other observations

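The tests of the matrix, acute phase and lipogenesis patterns in this part were chosen after the results were seen, while the splits of libraries were planned. The test of genes near Insr stood in for a planned two-sided test of changed genes by distance. It was one-sided and used gene order and an unadjusted p under 0.05. Erdr1, the 1 liver gene past the threshold, lies with Mid1 at the boundary of the pseudoautosomal region of the sex chromosomes, where copies are hard to tell apart, and has no stated link to insulin. In eWAT it had a log2 fold change of -0.88 (edgeR adjusted p = 0.398). Mid1, a ubiquitin ligase looked up for this reason after its values were seen, had -1.16 in liver and -0.76 in eWAT (edgeR adjusted p = 0.133 and 0.153). Both genes were thus lower in IR 4A by their means in both tissues, although Erdr1 passed in liver alone and Mid1 in neither. A strain difference at that region was not tested.

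In IR 4A liver, genes that insulin induces through SREBP1c (Srebf1, Fasn, Scd1) had positive fold changes, but none of them passed on its own (edgeR). Their list, de novo lipogenesis, was called by camera (adjusted p = 0.000328) but not with an estimated correlation (adjusted p = 0.661). Genes that insulin represses through FoxO1 did not move as a group (median 0.05, camera adjusted p = 0.891). Ide, which degrades insulin, had 0.55 in liver and 0.96 in eWAT, the eWAT groups not overlapping (edgeR adjusted p = 0.135 and 0.173).

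The lower matrix genes in eWAT of IR 4A were weighed against 3 technical explanations. Without WT 4 the difference was -1.01 against -1.23 with it, so most of the difference did not rest on WT 4. The exact permutation p of 0.0159 without WT 4 adds nothing to this. The groups already did not overlap with WT 4 in, so leaving it out could not give a large p. GC content and gene length are excluded as the whole cause (median -1.22 after the trend was removed against -1.28 before, camera adjusted p = 8.43e-33). Dilution of adipose RNA by RNA of the epididymis or testis cannot be told apart from a change in the tissue: the matrix level minus the adipocyte level did not differ (exact permutation p = 0.302, difference -0.25), and the adipocyte level itself overlapped between groups (p = 0.183, difference -0.98). Adipocyte markers took 1.37%, 0.944% and 1.23% of counts in IR 4A 1, 2 and 5, within the WT range of 0.813% to 2.53%. They took 0.269% and 0.406% in IR 4A 3 and 4. The matrix level of every IR 4A library lay below every WT library, by a narrow gap (at most 6.61 against at least 6.67). Low adipocyte RNA was thus seen in IR 4A 3 and 4 alone. The share of fat in each piece itself was not measured, which keeps dilution open.

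The lower acute phase genes in liver of IR 4A followed WT 1 (level 10.03) and WT 3 (9.18). All 3 of the other WT libraries (7.87 to 8.01) lay within the range of IR 4A (7.18 to 8.37), and the exact permutation p over the 10 libraries was 0.151, so the pattern is consistent with inflammation in 2 WT livers. GC content and gene length are excluded as the cause (median -0.89 before and after, camera adjusted p = 1.39e-06). A difference between the genotypes is not shown by these values.

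For the higher lipogenesis genes in liver of IR 4A, WT 1 and WT 3 as the whole cause cannot be told apart from a difference of the genotypes. Without them the levels of the groups did not overlap (6.97 to 7.09 in WT, 7.15 to 7.26 in IR 4A), but the exact permutation p of 0.0179 is unadjusted and the smallest that 3 libraries against 5 allow. The difference fell to 0.16 from 0.35 and the camera call ended (median 0.16 against 0.29, adjusted p = 0.0589, with 8 libraries against 10). GC content and gene length are excluded as the whole cause (median 0.26 after the trend was removed against 0.29, camera adjusted p = 7.58e-05). Feeding state at collection, which the labels do not give, stays open and could raise Scd1 in the same way.

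DNA carried over around the edited receptor gene was tested with the 50 tested genes nearest to Insr in gene order, all on 1 side because Insr comes first on its chromosome in the table. In liver 20% of them had an unadjusted p under 0.05 against 18.1% of other genes (one-sided Fisher's exact p = 0.419), which leaves it open. In eWAT the shares were 32% and 15.9% (one-sided Fisher's exact p = 0.00355), which goes with the explanation, although 4 of those 16 genes are of the Cd209 family of myeloid cells and 2 are Col4a genes, which move with the cell types above. Of the neighbours 2 had an unadjusted p under 0.05 in both tissues, 1 of them in the same direction, and 0 passed the adjusted threshold in either (edgeR).

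For each comparison 100 splits of the libraries were counted, the real one and 99 others, and each number of splits below includes the real one. For the liver genes past the threshold chance could not be excluded (1 gene, 7 splits, highest other 313, from the split that exchanged WT 2 and IR 4A 1). At an unadjusted p under 0.05, as many liver genes (2246) came from 2 splits alone (highest other 2750). These numbers of splits were not adjusted over the counts compared. In eWAT 3 splits called at least 2 genes past the threshold (highest other 2299). At an unadjusted p under 0.05, 7 splits gave at least 2615 genes (highest other 5441). Chance is not excluded for either count, as other splits of the same libraries went far above both. The highest eWAT splits, with 2299 and 2112 genes, put WT 1, WT 2, IR 4A 3 and IR 4A 4 together, the libraries with most testis RNA, which is a structure of the samples far larger than the genotype. List counts were not beyond chance in liver (16; 27 splits, highest other 26), eWAT (25; 40 splits, highest other 34) or the difference between tissues (24; 14 splits, highest other 32). For the difference between tissues 2 splits gave as many genes in all (354, highest other 430). By direction, the 246 smaller differences were compared with each split's larger count (2 splits, highest other 413). The 108 larger ones were compared with each split's smaller count (1 split, highest other 17). As the direction of a split is arbitrary, this does not exclude chance for 108 genes larger in eWAT. For genes changed in both tissues the splits say nothing, since the count was 0, which all 100 splits meet (highest other 0).

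The epididymis RNA in eWAT was weighed as a source of differences in other genes, which stays open. Its 16 markers took up to 5.38% of all counts, which for so few genes leaves room for a large share of the whole library to come from that organ, and with their level as a covariate the matrix list had a median of -0.83 against -1.28. The genes past the threshold lost their calls there, but Itgbl1 and Tnmd had -1.40 and -4.37 against -1.42 and -4.23 without it, so that loss does not speak for this source. The covariate sets WT 4 (2.89) apart from the other 9 libraries (9.42 to 10.41), and cannot separate epididymis RNA from any other trait of WT 4. The near absence of Gpx5, Lcn8 and Spag11b in WT 4, beside Crisp1 within the range of the other libraries, may reflect which end of the epididymis was cut with the fat, which no value here tests.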
